A study of Homo sapiens with 2 samples.

How the data were processed

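PAR-CLIP libraries from 293T cells were compared, 1 Mock library and 1 library from cells expressing RAD51AP1, grouped by the titles in the labels. Per the labels' protocols, cells were cultured for 14 h with 100 µM 6-SG, RNA was released from the recovered proteins with proteinase K and extracted with phenol and chloroform.

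The authors deposited gene counts, which are whole numbers of reads per gene without normalization. Per the submitters' processing notes, STAR 2.7.6a and featureCounts 2.0.2 were used with the T2T-CHM13 build. The first count table has the layout of STAR's own gene counts, with 3 columns: reads without regard to strand, on the strand of the first read, and on the opposite strand. It counts uniquely aligned reads only. The featureCounts table was made from exons of the T2T-CHM13 annotation with reads counted at every alignment and with pairs as fragments, per the file headers. The column on the strand of the first read held the minority of gene reads in both libraries and is called the minority strand. Whether the library kit keeps strand is not given in the sources used here.

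The deposited rDNA table holds a signal, taken from its values to be the coverage or depth at each of 13331 positions, and is not scaled between libraries. Its column names speak of bin starts and ends, which its content does not match. The BLAST settings, the rDNA reference sequence and the reads used are not given in the sources used here. Crosslink-induced base changes were not analysed here.

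The entries of the count table that name no gene held 90.7% of Mock reads and 95.2% of RAD51AP1 reads and were left out of gene totals. Of 64213 annotated genes, 28660 had a read in Mock and 29975 in RAD51AP1. The 11364 genes with at least 50 reads in both libraries together held 94.0% and 95.4% of gene reads. Counts were scaled to all gene reads. Ratios of RAD51AP1 to Mock were given exact Clopper-Pearson 95% intervals, from the share of a gene's reads that lay in 1 library. A gene was called higher at a ratio of at least 4 with a bound of at least 2, and the same rule was used in the other direction. Against a count of 0, folds were computed at 3 counts per library. No p-values were computed, since each group had 1 library.

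Before the data were examined, the genes to name were set as RAD51AP1, the 12 with the highest lower bound, the 12 with the lowest upper bound, the 5 with the most reads in each library, and members of 25 gene lists. The files give gene IDs without names, and 0 of the IDs matched the name tables used here, which belong to GRCh38 annotations. The RAD51AP1 transcript, the gene lists and RNA classes by biotype were therefore not analysed here. Genes were not matched by position either, so whether the transcript of the expressed protein is among the genes called higher was not determined. At most 2 IDs per direction are printed and other genes are given by coordinates. Classes by exon number and exon length, with limits at 200, 350 and 1000 nt, were chosen in place of biotypes after the files had been seen.

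Depth on the rDNA reference was averaged per block or spacer over positions with at least 50 reads in both libraries together, and in windows of 100 nt with a mean depth of at least 50 in both together. It was scaled to the total of each table. Blocks were stretches with a summed depth of at least 10000, merged over gaps of up to 500 nt and at least 1000 nt long, also chosen after the table had been seen. For block names, lengths of 5 RNA18SN and 5 RNA28SN genes were taken from the RefSeq annotation of GRCh38.p14.

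The rule was tested on simulated data for this comparison, with Poisson counts drawn at the real depths from a profile pooled over both libraries. Only counting error was simulated, so the results give no rate of false calls for the real libraries. The rule called 98% of 50 genes raised 8-fold and 100% of 50 genes lowered to 0.125. It called 52% of 50 genes raised 4-fold, 54% of 50 genes lowered to 0.25, and 0% of 11194 unchanged genes. The interval held the true ratio for 95.8% of the unchanged genes.

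To follow strand shares between libraries, the Mock reads of each gene were divided at random into 2 parts; genes were sorted on one part and the change to RAD51AP1 was measured from the remaining part. Genes with at least 10 reads in each part and in RAD51AP1 were used.

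Alternatives covered scaling, strand columns, the featureCounts table, read minimums, ratio limits, thinning of the deeper library, and rDNA scaling, minimum depth, window merging and block limits. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16 for TMM factors.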

Results

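RNA bound in 293T cells was profiled by PAR-CLIP, in which a thiol-containing nucleoside is built into RNA so that proteins can be crosslinked to it and recovered with their RNA. 293T is an established human line derived from fetal kidney cells. The cells received 100 µM 6-SG for 14 h, and complexes were recovered on streptavidin resin and Flag resin. RAD51AP1 is a DNA- and RNA-binding protein of homologous recombination. The 2 libraries were 1 Mock library and 1 library from cells expressing RAD51AP1, and the comparison asks which RNA was recovered with the protein above the mock background. With 1 library per group there was no replicate check and no test between conditions. Intervals of read ratios and read shares are exact 95% counting intervals. They cover counting error only, since PCR reads without molecular identifiers are not independent molecules. Where reads were counted at every alignment, 1 read can enter several times, so those intervals can be too narrow even for counting error.

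The Mock library held 17455971 reads and the RAD51AP1 library 53204289, a depth ratio of 3.05. Reads that were not aligned made up 45.5% of the Mock library and 55.1% of the RAD51AP1 library. Reads aligned at several places made up 23.9% and 23.2%. Uniquely aligned reads in 1 annotated gene numbered 1624042 in Mock, or 9.30% (9.29 to 9.32), and 2578368 in RAD51AP1, or 4.85% (4.84 to 4.85). The gene-level depth of the RAD51AP1 library was therefore 1.59 times that of Mock, less than its depth in all reads. Reads outside exons of annotated genes fell from 19.8% to 15.9% of the library.

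Ribosomal RNA recovered in the RAD51AP1 library was shifted from the 18S to the 28S part of the ribosomal DNA (rDNA) unit. The 28S block held 50.3% of the rDNA depth in Mock and 84.5% in RAD51AP1, and the 18S block 49.4% and 15.3%. Mean depth over the 28S block divided by that over the 18S block was 0.370 in Mock and 2.003 in RAD51AP1, a 5.41-fold change that does not depend on how the libraries are scaled. The table gives no boundaries: the blocks were found from the depth at positions 3669 to 5502 (1834 nt) and 7927 to 12970 (5044 nt). They were named from their order in the unit and from the annotated lengths of 18S genes (1869 nt) and 28S genes (5054 to 5077 nt). Together they held 99.7% of the depth in Mock and 99.9% in RAD51AP1.

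Before scaling, mean depth over the 18S block was 296465 reads per position in Mock and 345259 in RAD51AP1, whereas over the 28S block it was 109705 and 691595. Total rDNA depth was 3.75 times higher in RAD51AP1. Scaled to that total, the 18S block was 3.22-fold lower in RAD51AP1, with 18 windows of 100 nt at ratios of 0.186 to 0.365. The 28S block was 1.68-fold higher, with all 50 windows between 1.16 and 3.86. Scaled to gene reads, the ratios were 0.734 for the 18S block and 3.97 for the 28S block. These window ratios describe spread along the reference and not between replicates, as neighbouring positions share reads. Because the values are shares of 1 total, the 28S rise and the 18S fall are not independent.

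**Figure D1:**
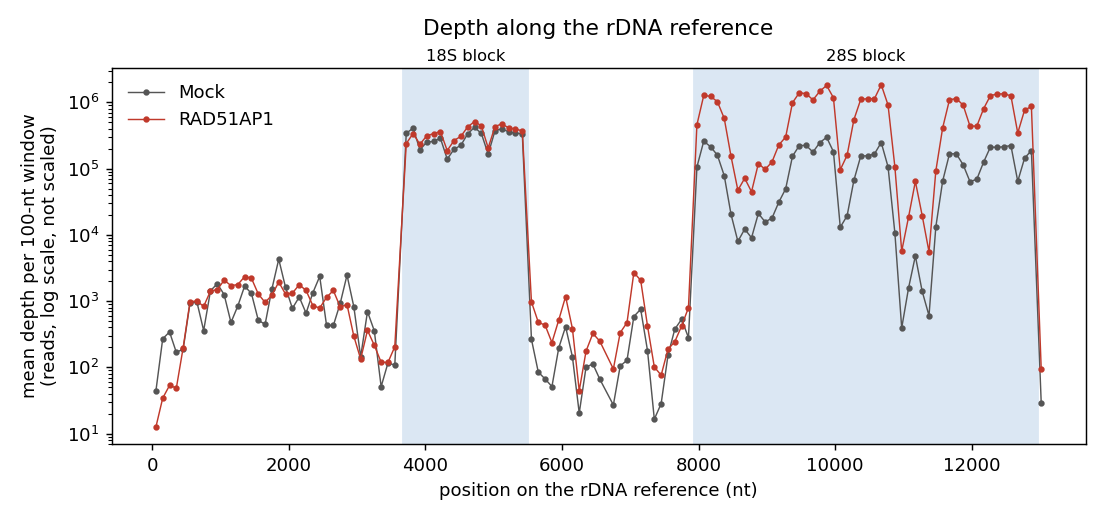
Mean depth per 100-nt window (reads, log scale, not scaled) against position on the rDNA reference (nt) for the Mock library (grey) and the RAD51AP1 library (red), with shading over the 18S and 28S blocks. The libraries lie close together over the 18S block (means 296465 and 345259) and apart over the 28S block (109705 and 691595).

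The ratio was uneven within each block. The highest 28S window, at positions 10927 to 11026, had a ratio of 3.86 at a mean depth of 393 in Mock and 5681 in RAD51AP1. The 5 windows of the 28S block with a Mock depth under 5000 had a median ratio of 3.56, and the other 45 had a median of 1.71 and a range of 1.16 to 2.65. The first window of the 18S block, positions 3669 to 3768, was 5.36-fold lower in RAD51AP1. The largest depth at a single position was 532854 at position 3773 in Mock and 2024095 at position 10665 in RAD51AP1.

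Spacers of the rDNA unit were covered at low depth in both libraries. The leading spacer, positions 1 to 3668, had a mean depth of 925 in Mock and 973 in RAD51AP1, and its scaled ratio was 0.281. Scaled to gene reads its ratio was 0.663, and before scaling 19 of its 36 windows were higher in RAD51AP1. The whole stretch between the blocks, positions 5503 to 7926, is called the internal spacer here, and any smaller rRNA within it was not separated. Its longest run without depth in either library was positions 6622 to 6723 (102 nt). It had a mean depth of 216 in Mock and 606 in RAD51AP1 and a scaled ratio of 0.747. Its windows ran from 0.173 to 1.73, with 5 of 23 above 1, and scaling to gene reads turned its ratio to 1.76, so no direction was assigned to it.

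**Figure D2:**
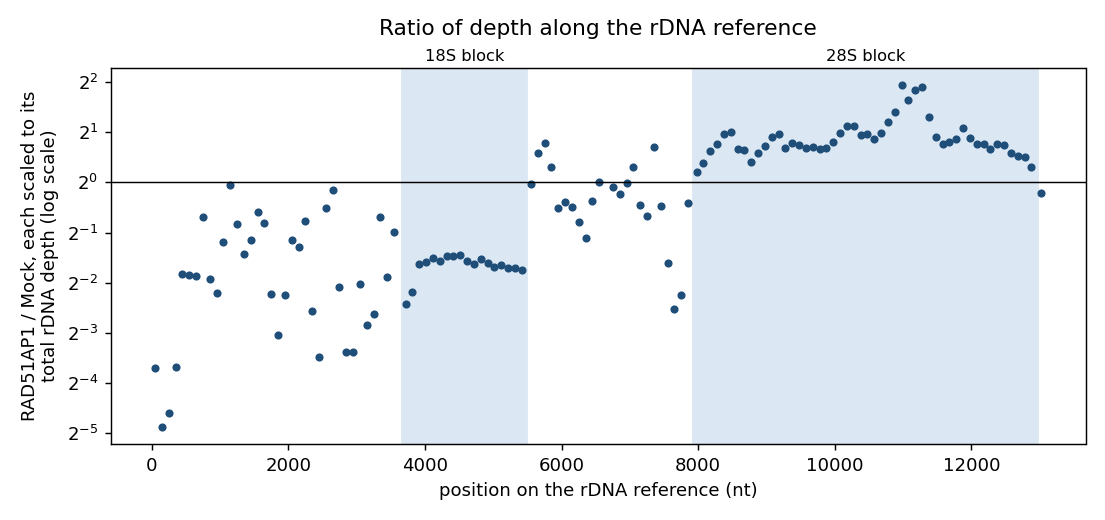
Ratio of depth in the RAD51AP1 library to that in Mock, each scaled to its total rDNA depth (log scale), against position on the rDNA reference (nt). Points are 100-nt windows, the line marks a ratio of 1 and shading marks the blocks: all 18 windows of the 18S block lie at or under 0.365 and all 50 of the 28S block at or above 1.16.

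Genes annotated as rDNA-length single exons were also counted. In all, 219 genes with 1 exon of 13318 to 13381 nt lay on chromosomes 13, 14, 15, 21 and 22 of the T2T-CHM13 assembly. Counted at every alignment, they held 1.20% of Mock gene reads and 2.20% of RAD51AP1 gene reads, a ratio of 1.83 (1.81 to 1.84). Over uniquely aligned reads the ratio was 3.48 (3.18 to 3.81), from 581 and 3210 reads. At every alignment the 219 genes held 68340 and 234451 reads, and 51 of them had no read in either library. These counts are small beside mean rDNA depths of 296465 and 345259 reads per position over the 18S block. They cannot stand for the rRNA reads as a whole.

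Across genes, 603 were higher in RAD51AP1 and 513 were higher in Mock, out of 11364 with at least 50 reads in both libraries together. A gene was counted when its scaled ratio was at least 4 and the near bound of its interval at least 2. The 603 genes held 2.91% of Mock gene reads and 14.6% of RAD51AP1 gene reads. The 513 genes held 9.41% and 1.00%. Single-exon genes made up 18.6% of the first set and 11.3% of the second, against 5.41% of all genes examined. Median exon length was 3447 nt, 4629 nt and 5354 nt in the same order. As genes were not named, the 603 may include the transcript of the expressed RAD51AP1 itself, which was not determined.

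The balance of these counts depended on scaling. With scaling to gene reads, 54.0% of the counted genes were higher in RAD51AP1, and the median gene had a log2 ratio of -0.32. Relative to that median gene, 1090 genes were higher in RAD51AP1 and 330 in Mock, or 76.8% higher in RAD51AP1. The share was 80.6% with median-ratio scaling, 79.2% with TMM scaling and 2.80% with scaling to all reads. Of the 603 and 513 genes, 317 and 309 were called again in the column for the majority strand. The minority-strand column gave 116 and 66, and the table that counts every alignment 169 and 322. Only 10013 genes had at least 50 reads in the majority-strand column and 4213 in the minority-strand column. Fewer genes could therefore be called there than among the 11364 of the main count. Without genes with most reads of both libraries together on the minority strand, 310 of the 603 were left.

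The gene with the highest lower bound was CHM13_G0051957, a single exon of 2481 nt on the plus strand of chromosome 7 (129309277 to 129311757). It had 4 reads in Mock and 221 in RAD51AP1, a ratio of 34.8 (13.4 to 129). In RAD51AP1, 100% of its reads lay on the strand that held the minority of gene reads, and the column for the other strand held 1 Mock read and 0 RAD51AP1 reads. Counted at every alignment it had 853 and 25091 reads, a ratio of 15.7 (14.6 to 16.8). The next, CHM13_G0013277 on the plus strand of chromosome 12 (95919901 to 95942718; 9 exons after merging), had 21 and 676 reads, a ratio of 20.3 (13.2 to 33.0), and 12.6 (9.81 to 16.5) at every alignment. The 12 genes with the highest lower bounds had ratios of at least 8.40, 9 of them had several exons, and 6 had most of their RAD51AP1 reads on the minority strand.

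At the other end, CHM13_G0017724 on the minus strand of chromosome 14 (99836763 to 99841427; 5 exons) had 139 reads in Mock and 0 in RAD51AP1. Against 3 counts as the limit that 0 allows, with the Mock count taken as exact, it was at least 73.6-fold lower in RAD51AP1; the exact interval, which also covers counting error in Mock, began at 59.0-fold. Counted at every alignment it had 752 and 78 reads and was 18.1-fold lower. CHM13_G0042073 on the plus strand of chromosome 4 (77084306 to 77087480; 3 exons) had 126 and 0 reads and was at least 66.7-fold lower on the same terms, with an interval beginning at 53.4-fold. At every alignment it had 261 and 3 reads, a ratio of 0.00612 (0.00125 to 0.0181). All 12 genes with the lowest upper bounds had several exons, at most 22 reads in RAD51AP1 and most of their Mock reads on the majority strand.

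The 5 most-read genes of each library made up 8 genes, of which 3 had a ratio above 1 and 5 a ratio under 1. By the rule above, 1 of these genes was counted as higher in RAD51AP1 and 1 as higher in Mock. The first, on chromosome 8 (1752470 to 1785512), had 4756 reads in Mock and 37914 in RAD51AP1, a ratio of 5.02 (4.87 to 5.18). Short of the rule, a gene on chromosome 19 (38102912 to 38126908) had 5794 and 29660 reads, a ratio of 3.22 (3.13 to 3.32). A gene on chromosome 16 (74059928 to 74098293), also short of it, had 2865 and 18143 reads, a ratio of 3.99 (3.83 to 4.15), with 90.1% of its Mock reads on the minority strand. The most-read gene of the Mock library, a 299-nt single exon on chromosome 14 (43784832 to 43785130), was lower, with 58519 reads in Mock and 3284 in RAD51AP1. It was 28.3-fold lower (27.3 to 29.3). Ratios under 1 ran from 0.0353 to 0.812, and included 0.444 (0.432 to 0.457) on chromosome 6 (74692854 to 74700895) and 0.624 (0.608 to 0.641) on chromosome 1 (92677155 to 92687066). The ratio of 0.812 (0.797 to 0.827), of a single-exon gene on chromosome 20 (30928555 to 30930414), turned to 1.09 with median-ratio scaling and to 1.06 with TMM scaling. Of the reads of that gene, 97.7% in Mock and 96.8% in RAD51AP1 lay on the minority strand.

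Gene classes by exon number and length also differed. Single-exon genes of over 200 to 350 nt held 4.01% of uniquely aligned gene reads in Mock and 0.326% in RAD51AP1, and were 12.3-fold lower. Most of that fall came from the 299-nt gene on chromosome 14: without it the ratio of the class was 0.493 (0.475 to 0.511). Genes of up to 200 nt had a ratio of 1.17 (1.14 to 1.21) over uniquely aligned reads and 0.200 (0.198 to 0.201) when every alignment was counted. The rise over uniquely aligned reads rested on 1 gene of 54 nt on chromosome X (107502054 to 107502107), with 1006 and 6429 reads; without it the ratio was 0.618 (0.594 to 0.642). That gene was singled out after its values were seen. Single-exon genes of over 1000 nt held 6.11% and 6.93% of reads, a ratio of 1.13. That ratio turned to 0.591 with scaling to all reads and to 0.722 in the first-read strand column. The 425 genes of this class with at least 50 reads had a median ratio of 1.76, with 80 higher in RAD51AP1 and 28 in Mock. Multi-exon genes held 87.4% and 90.3%.

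**Figure D3:**
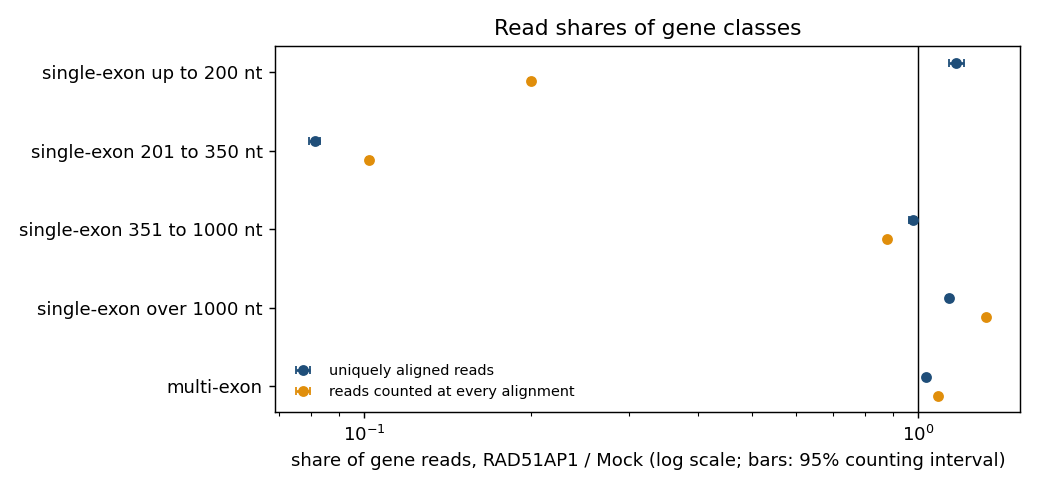
Share of gene reads in RAD51AP1 divided by that in Mock (log scale) for 5 classes of genes by exon number and length, from uniquely aligned reads (blue) and from reads counted at every alignment (orange). Bars are 95% counting intervals, many smaller than the points, and the orange ones treat repeated counts of a read as independent. Genes of up to 200 nt lie at 1.17 in the first count and 0.200 in the second, and genes of over 200 to 350 nt at 0.0813 and 0.102.

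Short genes of a few fixed lengths carried most of the Mock reads counted at every alignment in these classes. Genes of 299 nt fell from 190138 reads in Mock to 10707 in RAD51AP1, or 33.4-fold after scaling. Genes of 164 nt fell from 166464 to 35782, or 8.74-fold, and over uniquely aligned reads by a similar 8.72-fold, from 1368 to 249. Genes of 191 nt fell from 135551 to 44754, or 5.69-fold. Nearly all of the latter lay in 8 copies spaced 6145 to 6173 nt apart on chromosome 17 (44122352 to 44165647). Only 2 and 8 of their reads aligned uniquely, so that fall could not be checked without reads shared between copies. Among genes of 295 nt, 1 gene on chromosome 3 (15740969 to 15741263) was lower in both counts, 28.2-fold at every alignment and 7.98-fold over uniquely aligned reads. Pooled, the other 54 genes of that length were higher in both counts, with ratios of 2.72 (2.49 to 2.99) and 3.68 (3.28 to 4.14). Few of the 55 genes held many reads. At every alignment 5 had at least 50 reads, 3 of them lower in RAD51AP1, and over uniquely aligned reads 2 did, 1 of them lower.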

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

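In this part, the tests of 28S against 18S depth, of strand information, of the strand rise with and without overlapping genes, of reads with several alignments and of rRNA share were chosen after the results were seen. The test of overlap among the 296 genes with most RAD51AP1 reads on the minority strand was fixed before its result was seen.

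Both of the results singled out here are signals that exceeded Mock and that the main gene comparison did not separate. Minority-strand reads made up 37.7% of RAD51AP1 gene reads against 24.6% in Mock. They are not outside the main comparison, which counted reads without regard to strand. Of the genes it called higher in RAD51AP1, 296 had over 50% of their RAD51AP1 reads on the minority strand. The rDNA-length single-exon genes held 2.20% of RAD51AP1 reads counted at every alignment against 1.20% in Mock. The main comparison used only uniquely aligned reads, and those of the rDNA-length genes were part of its gene totals.

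The 28S block rose 5.41-fold relative to the 18S block. Saturation of depth would give equal ratios at equal Mock depth, but at a Mock depth of 200000 to 300000 the 28S windows rose 4.70 times as much as the 18S windows. A few extreme positions were argued against too, since 100% of 28S windows lay above the highest 18S window. A difference between single libraries unrelated to RAD51AP1, such as in fragmentation or rRNA recovery, cannot be told apart from an effect of the protein with 1 library per condition. Recovery of 28S rRNA with RAD51AP1 therefore stays a hypothesis, open beside that explanation.

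Minority-strand reads rose from 16.2% to 33.4% of pooled reads in genes higher in Mock and from 22.04% to 34.6% in genes higher in neither library. They stood at 45.6% and 48.2% in the 603 genes higher in RAD51AP1. The share of the median gene went from 6% to 17.4%, from 11.4% to 17.5% and from 44.4% to 47.1% in the same order. Pooled shares also depend on how reads are spread over genes, which was not separated here. A gene annotated on the other strand was argued against as the whole cause of the pooled rise. That rise in genes without such an overlap was 0.784 times that in genes with one. The 296 genes higher in RAD51AP1 with over 50% of their RAD51AP1 reads on the minority strand overlapped one 0.991 times as often as other tested genes. That value cannot bear on the rise, since most of the 296 were over 50% in Mock too. Added reads of either strand would pull every gene toward 50%; with genes sorted on a random part of the Mock reads and the change measured from the remaining part, 8872 genes with 50% or less had a median change of 5.20 percentage points (4.97 to 5.45), whereas 1262 genes with over 50% (median 79.9% in Mock and 84.0% in RAD51AP1) had a median change of 0 (-0.375 to 0.538). The same admixture in every gene would have changed the latter by -3.79 points, which argues against it; an admixture that differs between genes stays open, and the 45.4% of the 603 genes whose share lay above 50% with its interval does not bear on the rise, since 250 of the 296 were over 50% in Mock too. Unannotated transcripts, genomic DNA and a biological explanation were not tested.

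Short single-exon genes were lower in RAD51AP1, and counting of reads with several alignments was weighed as a cause in 2 forms. The first form used class sums over uniquely aligned reads: the ratio was 0.0813 for genes of over 200 to 350 nt, which argued against it, and 1.17 for genes of up to 200 nt, where the fall was absent without shared reads. Once those sums were seen to rest on 1 gene each (ratios without it 0.493 and 0.618), medians over genes were added as a second form, giving 0.410 (0.295 to 1.13, 24 genes) and 0.231 (0.120 to 0.900, 26 genes). Both intervals span the limit of 0.5, so the second form decided neither class. The ratio of 0.115 (0.0998 to 0.131) for 164-nt genes over uniquely aligned reads, with 5 of 5 genes lower, argued against the explanation for that length, and it stays open for the 191-nt genes, of which 2 and 8 reads aligned uniquely. A larger rRNA share in RAD51AP1 was weighed as another cause. The ratio for over 200 to 350 nt was 0.0788 times that of multi-exon genes, a value that rests on the same gene. Both ratios are of shares of gene reads, and multi-exon genes held 87.4% and 90.3% of these. The value therefore nearly repeats the 0.0813 above and cannot decide on the rRNA share.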

How the results depend on the processing

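Settings that leave out minority-strand or overlapping genes, and scaling of rDNA to all reads, other block limits and windows without low depth, were chosen after seeing the data. Numbers of genes higher in RAD51AP1 and in Mock (603 and 513) became 1253 and 301 with median-ratio scaling, 1179 and 310 with TMM scaling, 76 and 2639 with scaling to all reads, 212 and 296 in the first-read strand column, 289 and 138 at a minimum of 200 reads, 2285 and 2857 at a ratio of 2, 60 and 169 at a ratio of 8, and 285 and 209 without overlapping genes. Leaving out genes with most reads of both libraries together on the minority strand gave 310 higher in RAD51AP1. Genes higher in Mock numbered 902 in the featureCounts table, 1239 at a minimum of 10 reads and 1430 with none. The opposite-strand column, which holds the majority of gene reads, called 680 and 375 genes and shared 317 of the 603 and 309 of the 513. The first-read strand column shared 116 and 66. Fewer genes could be called in these columns, with 10013 and 4213 tested in the same order. The featureCounts table shared 169 of the 603 genes and 322 of the 513. Median-ratio scaling kept all 603 and 301 of the 513. It raised every ratio by the same factor, so by construction no call higher in RAD51AP1 could be lost and none higher in Mock gained. A changed number of genes tested (4374 at a minimum of 200 reads, 18256 at 10 and 34984 with none) or a changed limit accounts for the read minimums and ratio limits by construction. For the others the cause was not tested.

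For classes of up to 200 nt, over 200 to 350 nt and over 1000 nt, ratios (1.17, 0.0813 and 1.13) became 0.610, 0.0424 and 0.591 with scaling to all reads, 0.921, 0.366 and 0.722 in the first-read strand column, 1.30, 0.0922 and 1.44 in the opposite column, and 0.200, 0.102 and 1.32 in the featureCounts table. Without the 10 most-read genes, the latter classes gave 0.485 and 1.38. The log2 ratio of CHM13_G0051957 was -1.96 in the opposite-strand column, from 1 Mock read and 0 RAD51AP1 reads, which carries no direction. That of CHM13_G0017724 was -4.17 in the featureCounts table and, from 2 and 0 reads, -3.59 in the first-read strand column. Scaling rDNA to gene reads gave 0.663 for the leading spacer, 0.734 for the 18S block, 1.76 for the internal spacer and 3.97 for the 28S block, and scaling to all reads gave 0.382 for the 18S block. The 18S block stayed under 1 and the 28S block above 1 in each rDNA setting run. The cause of these moves was not tested.

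Alternatives planned for the RAD51AP1 transcript and the gene lists gave no value, because IDs could not be paired with names. No paired analysis was possible because each group has 1 library.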

Other observations

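Tests of neighbouring genes in this part were fixed before their results were seen; the chromosome and strand values were chosen afterwards. Genes of some chromosomes stood higher in RAD51AP1 than the median gene (ratio 0.800). Chromosome 19 held 7.22% of Mock gene reads and 10.1% of RAD51AP1 gene reads, a ratio of 1.40 (1.39 to 1.41), and its median gene had a ratio of 1.06. There, 46 of 722 genes (6.37%) were higher in RAD51AP1 and 21 in Mock. Over all genes examined 5.31% were higher in RAD51AP1, and on chromosome 18 7.22%, so the share called did not set chromosome 19 apart. Among chromosomes with at least 100 genes examined, median ratios were also 1.02 on chromosome 22 and 0.989 on chromosome 16, against 0.682 on chromosome 5 and 0.692 on chromosome 3. Mitochondrial gene reads had a summed ratio of 1.00 (0.879 to 1.14), and the 5 mitochondrial genes examined had a median ratio of 1.26.

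Genes with over 50% minority-strand reads in RAD51AP1 numbered 2253 and had a median ratio of 1.81, while the 9110 with 50% or less had a median ratio of 0.705. This split uses the RAD51AP1 reads that also enter the ratio, so it can raise the first value. Split on the share in Mock, 1611 genes with over 50% had a median ratio of 2.28 and 9751 with 50% or less had 0.732. The Mock reads enter the ratio as well, so this split is not independent of it either.

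The hypothesis that counted genes lie near one another was tested against 10000 random gene sets matched on read number. Of the 513 genes higher in Mock, 53 had another such gene within 100 kb, against a median of 42 (26 to 60) in random sets. Of the 603 genes higher in RAD51AP1, 61 did, against 62 (42 to 83). Both numbers lay within the central 95% of random sets, so no grouping beyond chance was found.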
